A study of Drosophila melanogaster with 4 samples.

How the data were processed

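Whole wandering larvae of the third instar were collected from 2 stocks, Oregon R+ (control) and a homozygous Hsromega mutant (hsromega66). Per the labels' protocols, RNA from 5 larvae was depleted of ribosomal RNA with a stranded total RNA kit and sequenced as paired reads of 100 bp, with 2 libraries per genotype. Per the submitters' processing notes, TopHat, Bowtie, Cufflinks and Cuffdiff 2.1.1 were used with genome build dm6. Whether counting used the strand of the reads is not given in the sources used here.

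Per the file headers, the authors deposited 1 FPKM value per transcript and genotype, pooled over the libraries of each genotype. The authors' deposited table also holds a log2 fold change of hsromega66 over control, a p-value and a q-value for each of 21529 transcripts. These columns were checked against one another. The deposited log2 values equal the log2 ratio of the FPKM columns within 0.0001, and the q-values equal Benjamini-Hochberg adjusted p-values over all 21529 transcripts within 1e-06. The smallest deposited p-value, 5e-05, was shared by 197 transcripts, so these cannot be ranked by p. Every transcript had an FPKM of at least 0.669 in 1 genotype, so transcripts low in both were not part of the values analysed. The deposited classes of all 21529 transcripts follow an unadjusted p of at most 0.05 with an absolute log2 ratio of at least 2, and a separate class for transcripts at 0 in 1 genotype. The summed FPKM was 971699 in control and 932179 in hsromega66. The differential and condition-specific tables held 208 and 365 rows, all of them also in the full table.

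Depth per library is unknown, because FPKM carries no counts. FPKM times length of single-exon transcripts at loci with 1 listed transcript was searched for the step that 1 read would make. At the best step, 25.6% of 767 control values and 21.5% of 808 hsromega66 values lay within 10% of a step of a whole multiple, where chance gives 20%, so reads were not recovered. With 1 pooled value per genotype, no standard deviation, leave-one-out value, replicate block or test of separate libraries could be computed. Nothing in the labels says whether the libraries came from separate cultures, so the deposited p-values are not known to cover a spread between cultures. How the spread between libraries entered the deposited test cannot be seen from the pooled values. Because raw counts and values per library were not used here, the design kept for pooled values was applied.

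FPKM values were summed over the listed transcripts of a gene, and ratios are log2(FPKM + 1) of hsromega66 minus that of control, which understates changes of low genes. A gene was called where the deposited q-value of at least 1 transcript was at most 0.05, with no filter on FPKM, and no gene had calls in both directions. Of the 12116 genes, 7419 had 1 listed transcript. The files' gene identifiers were matched to the Ensembl 115 annotation of BDGP6.54, which has dm6 coordinates: 12037 matched, and 12010 of these lay inside the locus given in the files. Distances to Hsromega used these coordinates.

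For 33 gene lists, fixed before the data were examined, the median log2 ratio of members with an FPKM of at least 1 in at least 1 genotype (11607 genes in all) was placed among 10000 random lists, drawn with replacement, of the same size and matched on mean expression in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above 97.5, and lists under 5 measured genes were counted only. The percentile describes these pooled values and is no p-value. In a test on permuted log2 ratios of these 11607 genes, lists of 30 genes stood apart in 6 of 100 cases with no shift, in 91 with a shift of 0.2 and in 100 with a shift of 0.5. Permuting removes any shared variation among the members of a list. The test therefore does not show how often lists of co-expressed genes stand apart with no shift. Calls within a list were also recomputed by Benjamini-Hochberg adjustment of the deposited p-values over the list alone. Lists do not all hold separate genes: Cyp18a1 and mag each stand in 2.

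Genes were named by a rule: Hsromega and the listed genes within 100 kb of it; the 10 largest rises and 10 largest falls with an FPKM of at least 1 and above 0 in both genotypes; up to 2 called members of each list, or its most extreme member; Hsp83, l(2)gl, Ras85D, roX1 and roX2; and for each genotype the 5 highest transcripts listed at 0 in the other. Further list members, near-identical copies and the genes of the closing section were named after their values were seen. Alternatives were another pseudocount, FPKM filter, q threshold, minimum ratio and centring, given in the closing section. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.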

Results

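The transcriptome of whole wandering larvae of the third instar of Drosophila melanogaster was compared between 2 genotypes. The control was the wild-type stock Oregon R+, and the other stock, hsromega66, was a mutant of the long noncoding RNA gene Hsromega, whose nuclear transcripts organise the omega speckles that hold hnRNP proteins. Each genotype was sequenced as 2 total RNA libraries, and each library came from 5 larvae. The values analysed here were the authors' pooled values, 1 FPKM for each transcript in each genotype, for 21529 transcripts of 12116 genes. The sequencing depth of the libraries is unknown, because the tables hold no counts. FPKM values below are the authors' values, summed over the listed transcripts of a gene. A gene was said to rise or fall only where the authors' deposited table gave 1 of its transcripts a q value of at most 0.05.

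The first question was whether the mutated gene was expressed in the mutant larvae. Hsromega (FBgn0001234, a long noncoding RNA gene on the plus strand of 3R, 21296127 to 21317836, dm6) was listed at 232 FPKM in control and 0.290 FPKM in hsromega66 larvae, a ratio of 799. Both of its listed transcripts were low in the mutant: 184 against 0.259 FPKM for the more abundant and 47.2 against 0.0303 FPKM for the other. Neither passed the threshold in the authors' deposited table, where their q values were both 0.998 and their p-values 0.0903 and 0.139. The pooled values therefore match the genotype labels in direction, and the level in each library was not analysed here.

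Of the 38 other listed genes within 100 kb of Hsromega, 16 of them entries of the trans-spliced mod(mdg4) locus, 2 passed the threshold. The gene e (ebony, the enzyme that joins beta-alanine to dopamine in pigment and cuticle metabolism; 3R, 21229839 to 21237177) lay 58950 bp from Hsromega and rose from 11.0 to 75.2 FPKM, with q = 0.00546 in the authors' deposited table. The noncoding gene lncRNA:CR46046, 83818 bp away, fell from 0.931 FPKM to a listed value of 0, with q = 0.00983 in the authors' deposited table. The remaining 36 genes had log2 ratios between -1.16 (CG6475) and 1.61 (pre-mod(mdg4)-AE), and their lowest q in the authors' deposited table was 0.441. The mod(mdg4) entries overlap one another, partly on opposite strands, so their single values are uncertain.

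**Figure D1:**
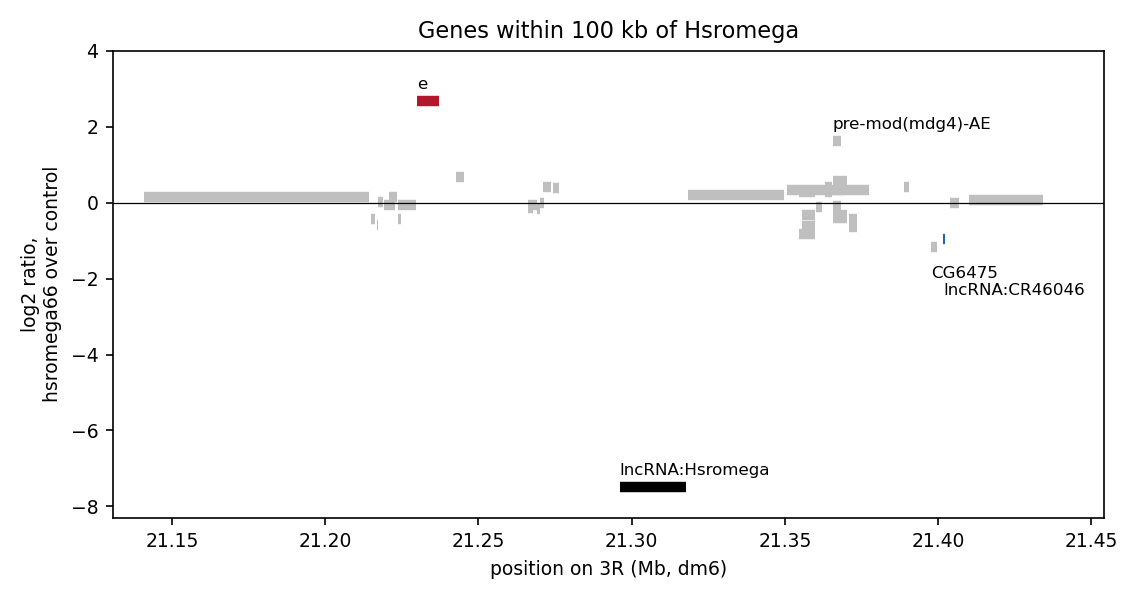
Log2 ratio of hsromega66 over control, on log2(FPKM + 1), against position on 3R (Mb, dm6) for Hsromega (black) and the 38 listed genes within 100 kb of it; each bar spans 1 gene, red marks a rise and blue a fall past the deposited q of 0.05, and grey marks the rest. Hsromega lies at -7.49 and e at 2.67, while the grey bars stay between -1.16 and 1.61.

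Across the transcriptome, 170 genes rose and 110 fell in hsromega66 larvae, 280 of 12116 in all, by the authors' Cuffdiff q values. Their median log2 ratio was 1.66 among the genes that rose and -1.64 among those that fell, and 59 of the former and 38 of the latter changed by at least 2 on the log2(FPKM + 1) scale. The 10 largest rises included the cytochrome P450 gene Cyp4e3 (0.305 to 42.6 FPKM), ninaD, a scavenger receptor used in carotenoid uptake (0.943 to 50.0 FPKM), the attacin gene AttC (5.26 to 118 FPKM) and the mucin gene Muc55B (5.00 to 72.8 FPKM). The others were CG32284 (4.06 to 100.2 FPKM), CG2070 (1.17 to 30.9 FPKM), CG7587 (251 to 3163 FPKM), CG42825 (1.40 to 28.8 FPKM), CG8087 (3.60 to 56.0 FPKM) and asRNA:CR45629 (8.15 to 341 FPKM). The last lies antisense to CG15308, listed at 0.000114 and 68.5 FPKM, and whether counting used strand was not given in the sources used here. The 10 largest falls included immune-induced peptide genes: IM23 (469 to 11.9 FPKM), IM4 (482 to 13.8 FPKM), IM2 (2225 to 84.8 FPKM) and IM3 (1569 to 120.2 FPKM), and CG15067 (220.1 to 16.2 FPKM) and CG16836 (281 to 21.4 FPKM), which lie beside IM2 and IM3. CG13560 had the largest fall, from 86.5 to 1.13 FPKM. The Turandot stress gene TotC fell from 63.0 to 4.38 FPKM, the alpha-tubulin gene alphaTub85E from 154 to 16.3 FPKM and CG1208 from 93.1 to 5.54 FPKM. In the authors' deposited table, all but 1 of these genes stood at its smallest q, 0.00546, shared by 197 transcripts, and CG2070 had a q of 0.0366.

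**Figure D2:**
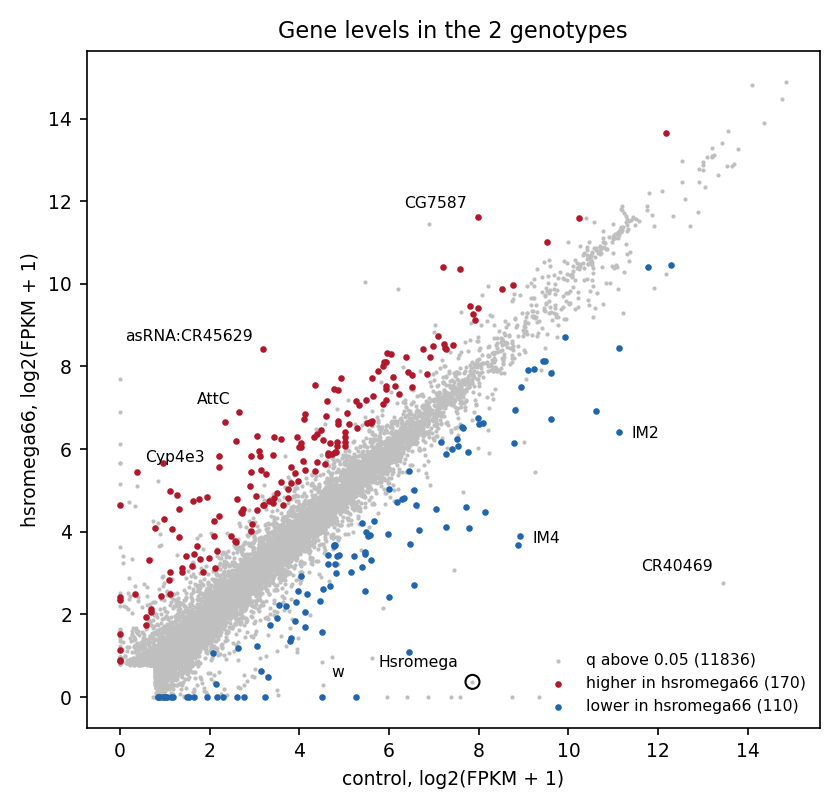
Level of each of the 12116 genes in control (horizontal axis) and hsromega66 larvae (vertical axis), both as log2(FPKM + 1); red and blue points are the 170 genes that rose and the 110 that fell at a deposited q of at most 0.05, and the ring marks Hsromega. Hsromega, w and CR40469 lie far below the diagonal among the grey points, which did not pass the threshold.

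Immune-induced peptides changed in both directions. Among 28 measured genes of the list, 6 rose and 8 fell by the deposited q, and 8 rose and 8 fell when adjusted over the list alone. The rises were AttC, AttD (1.49 to 22.4 FPKM), AttB (6.62 to 56.1 FPKM), Dro (drosocin; 7.72 to 56.2 FPKM), DptB (diptericin B; 39.5 to 134 FPKM) and the drosomycin-like gene Drsl2 (27.9 to 171 FPKM). Attacins, diptericins and drosocin are textbook targets of the Imd pathway. The falls were IM23, IM4, IM2, IM3, TotC, IM1 (778 to 105 FPKM), IM14 (2228 to 351 FPKM) and Drs (drosomycin, a textbook Toll target; 5028 to 1415 FPKM). AttB has a near-identical neighbour, AttA, listed at 15.7 and 23.8 FPKM, and the division of reads between them is uncertain. The list's median log2 ratio was 0.39, above all 10000 random lists, while its mean was -0.26. Of its members, 15 lay above 0 and 13 below. The list left out 6 further expressed peptide genes of the Bom family near IM1, which carry CG symbols here. All of these lay below 0, with a median of -2.73, so the list's high median depends on which members were listed. With genes of at least 5 FPKM the median was 0.041, at percentile 69.9. In the list of Toll and Imd pathway and recognition genes, 1 of 30 measured members passed the threshold, and 3 fell when adjusted over the list alone. It was SPE, the protease that activates the Toll ligand, which fell from 36.0 to 9.57 FPKM. The list's median was -0.0083, at percentile 43.6.

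**Figure D3:**
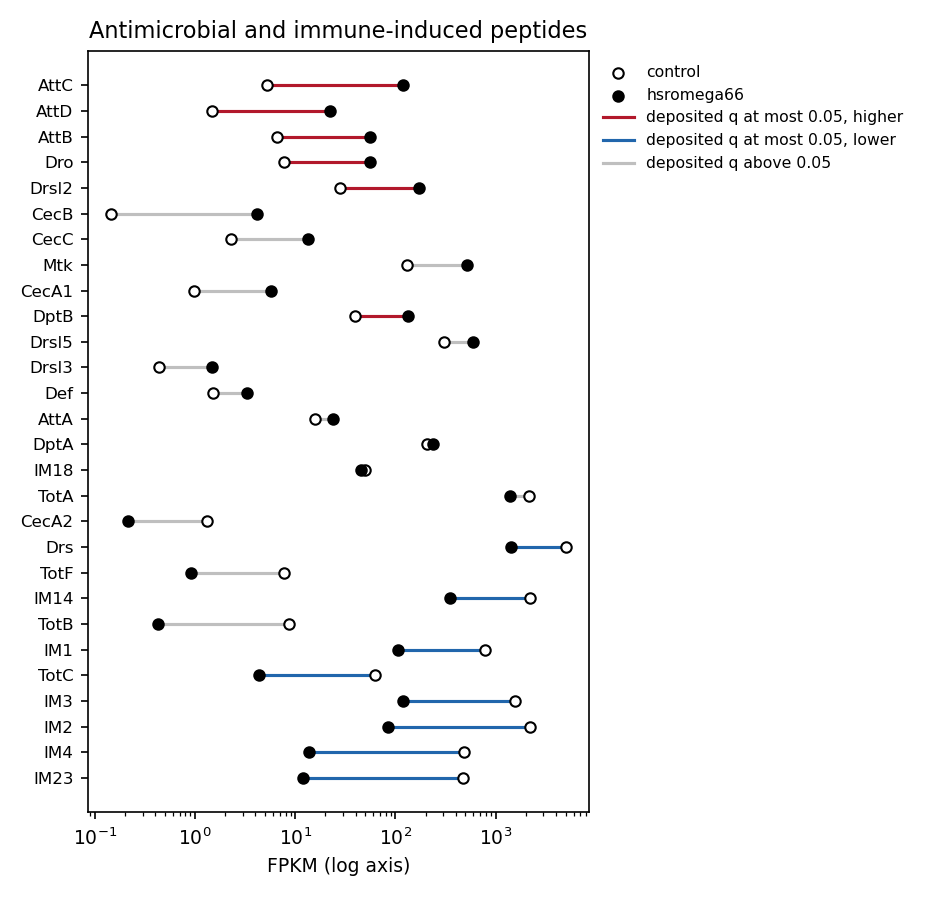
FPKM (log axis) of the 28 measured immune-induced peptide genes in control (open points) and hsromega66 larvae (filled points), with 1 pooled value per genotype and no error bars; line colour gives the deposited call. Attacin, drosocin and diptericin genes at the top were higher in the mutant and the IM genes at the bottom were lower.

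Digestive enzymes of the gut were higher in hsromega66 larvae as a list: 11 of 50 measured genes rose and 3 fell by the deposited q, and 19 rose and 4 fell when adjusted over the list alone. The largest rises were Bace (7.32 to 78.9 FPKM) and Amy-d (16.2 to 105 FPKM), an alpha-amylase gene whose near-identical copy Amy-p also rose (21.3 to 87.6 FPKM), so the division of reads between them is uncertain. The serine protease genes Ser6 (1.48 to 13.7 FPKM), Jon99Fii (734 to 2062 FPKM) and alphaTry (149 to 369 FPKM) rose as well, whereas Jon66Cii (782 to 230 FPKM), Jon99Cii (3524 to 1348 FPKM) and Mal-A4 (26.9 to 11.9 FPKM) fell. Lysozyme genes with near-identical copies had the largest ratios of the list without passing the threshold: LysD was listed at 117 and 2789 FPKM and LysC at 43.3 and 1062 FPKM, with q values of 0.0684 and 0.998 in the authors' deposited table. The list's median log2 ratio of 0.65 lay above all 10000 random lists. In the same larvae the medians of the muscle and haemocyte lists were -0.47 and -0.57.

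Genes of xenobiotic metabolism were divided. Of 71 cytochrome P450 genes, 8 rose and 3 fell by the deposited q, and 12 rose and 7 fell when adjusted over the list alone. Beside Cyp4e3, the largest rise was in Cyp309a1 (9.78 to 77.5 FPKM), followed by Cyp28a5 (6.56 to 42.5 FPKM). The falls were in Cyp12c1 (12.9 to 1.55 FPKM) and the near-identical pair Cyp12d1-p (16.6 to 3.15 FPKM) and Cyp12d1-d (3.89 FPKM to a listed 0). The list's median was 0.12, at percentile 99.8, and with genes of at least 5 FPKM it was 0.064, at percentile 91.8. Among 42 glutathione transferase and UDP-glycosyltransferase genes, 2 rose and 4 fell, led by GstD10 (100.3 to 15.6 FPKM) and GstD3 (27.1 to 6.99 FPKM), and 2 rose and 5 fell when adjusted over the list alone. This median was -0.065, at percentile 15.7. In the list of oxidative stress and iron genes 1 of 19 passed the threshold, also when adjusted over the list alone: the metallothionein gene MtnB, which fell from 184 to 66.6 FPKM, with a list median of -0.018 at percentile 50.5.

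Cuticle, moulting and secretion genes followed. Among 58 cuticle protein genes, 4 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. Of these, 3 of the rises lay in the 47E cluster, such as Cpr47Eb (2.11 to 26.0 FPKM), and the fall was in Cpr65Av (21.5 to 1.98 FPKM). The list's median was 0.097, at percentile 98.3, and with genes of at least 5 FPKM it was 0.018, at percentile 58.2. Among 23 ecdysone response genes, the nuclear receptor gene Eip78C rose (22.8 to 48.8 FPKM) and Eip55E fell (197 to 91.2 FPKM), and the same 1 rise and 1 fall stood when adjusted over the list alone. The median was 0.14, at percentile 96.9, and with a pseudocount of 0.1 it was 0.17, at percentile 97.9. Of 10 expressed genes of ecdysone synthesis and turnover, 1 rose, also when adjusted over the list alone: Cyp18a1, an enzyme that inactivates ecdysteroids (2.31 to 11.5 FPKM). The median of this list was -0.11, at percentile 14.2. Salivary gland glue genes had a median of -0.69, at percentile 0.03. Of the 10 measured, 1 fell by the deposited q and 2 when adjusted over the list alone. Sgs1 fell from 10.7 to 3.67 FPKM, and Sgs3 was listed at 863 and 416 FPKM with q = 0.0783 in the authors' deposited table. Sgs7, at 29798 and 30487 FPKM, differed little. Among 11 larval serum and fat body genes the yolk protein gene Yp3 rose (19.9 to 81.0 FPKM), the 1 call also when adjusted over the list alone, and the median was -0.019, at percentile 44.0.

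Lists of muscle, blood cell and energy metabolism genes lay low in hsromega66 larvae with few single calls. The 22 muscle genes had a median log2 ratio of -0.47, at percentile 0.02, and 20 of them lay below 0. The most extreme was TpnC25D, a troponin C gene (43.3 against 23.1 FPKM). None passed the deposited Cuffdiff threshold, and 1 had an unadjusted p of at most 0.05. The 13 haemocyte genes had a median of -0.57, below all 10000 random lists. None passed, and 5 were lower at an unadjusted p of at most 0.05 in the deposited Cuffdiff values. PPO3, a prophenoloxidase gene, stood at 14.4 and 1.23 FPKM, and the haemocyte marker Hml at 49.3 and 24.8 FPKM. Glycolysis and sugar metabolism genes had a median of -0.47, below all 10000 random lists. Of these 23, 1 passed the threshold, also when adjusted over the list alone: Ldh, lactate dehydrogenase, which fell from 254 to 106 FPKM. Nuclear genes of oxidative phosphorylation (86 genes, median -0.20) and mitochondrial ribosomal proteins (73 genes, median -0.14) also lay below all 10000 random lists. None of either list passed the deposited Cuffdiff threshold, and 3 and 2 of their members were lower at an unadjusted p of at most 0.05. Of all 21529 transcripts, 968 had such a Cuffdiff p in either direction. The muscle, haemocyte, oxidative phosphorylation and mitochondrial ribosomal lists held 106, 31, 180 and 89 transcripts. Of these lists, only the haemocyte count lay above the share over all transcripts. ND-MNLL was listed at 15.8 and 6.67 FPKM, and mRpS28 at 12.8 and 2.16 FPKM. The 15 genes of the mitochondrial genome had a median of 0.46, at percentile 99.9. None passed over all transcripts, and 1 did when adjusted over the list alone, mt:Cyt-b (270.0 and 850.1 FPKM). The largest ratio was that of mt:ND3 (11.8 and 56.0 FPKM). Cytosolic ribosomal protein genes had a median of 0.14, at percentile 99.8. Of these 90, 77 lay above 0 and none passed. In the deposited Cuffdiff values, 1 had a transcript that was lower at an unadjusted p of at most 0.05. This was a minor transcript of RpL32 (1.34 FPKM to a listed 0), while the gene as a whole stood at 2304 and 2458 FPKM. RpL37b had the largest ratio (11.0 and 16.1 FPKM).

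**Figure D4:**
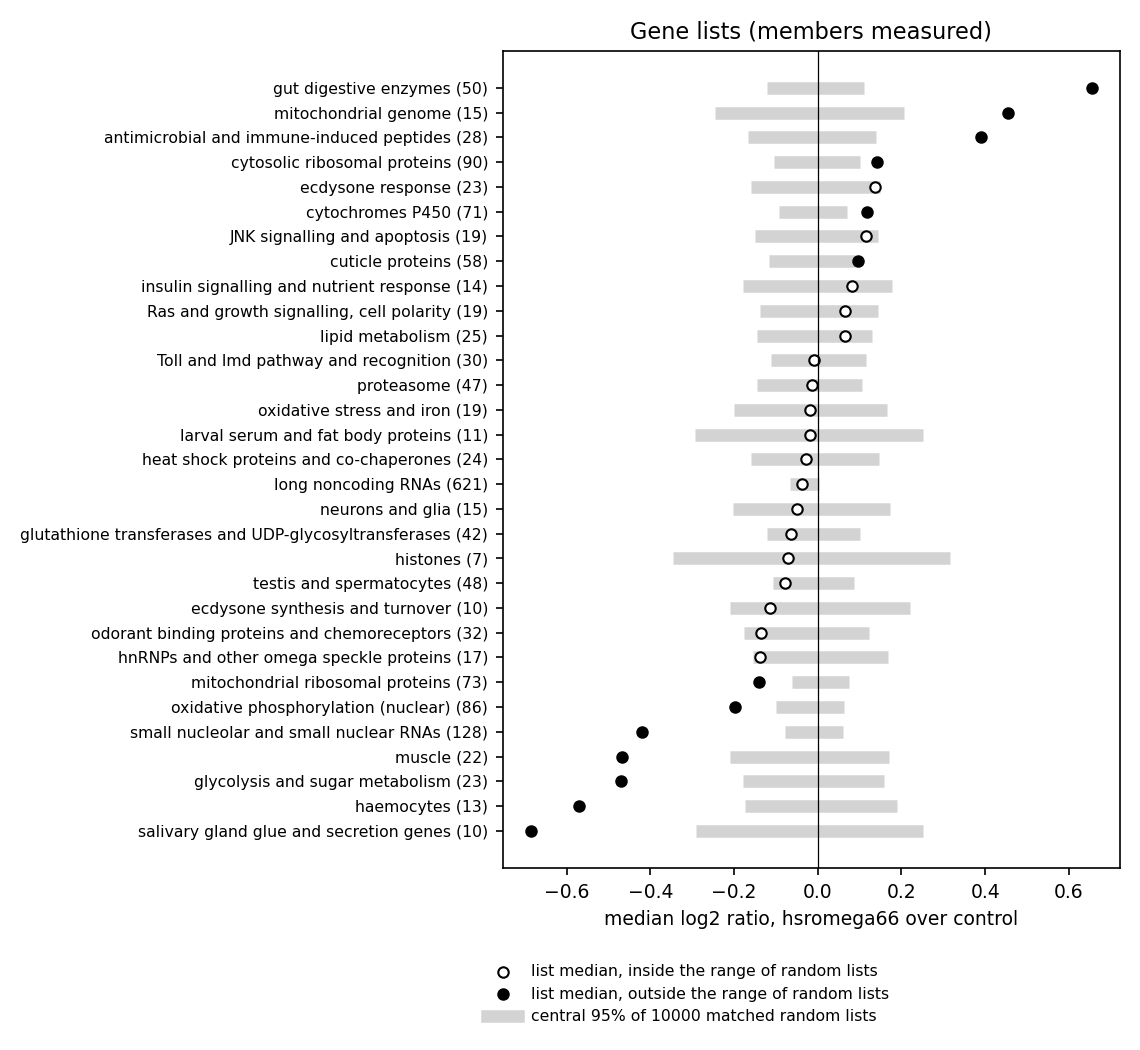
Median log2 ratio of hsromega66 over control, on log2(FPKM + 1), for the 31 lists with at least 5 measured genes (points; number of genes in brackets), against the central 95% of 10000 random lists matched on size and expression (grey bars). Filled points, outside the bars, are 6 lists above and 7 below, from gut digestive enzymes at 0.65 to salivary gland glue genes at -0.69. The immune peptide list, above the bars, left out 6 Bom peptide genes with a median of -2.73.

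Heat shock, hnRNP, Ras and JNK genes gave no calls. None of 24 heat shock and co-chaperone genes passed the deposited Cuffdiff threshold, and Hsc70-2, with the largest ratio (5.44 and 11.1 FPKM), was the 1 with an unadjusted p of at most 0.05. Hsp83 was listed at 630.0 and 540.1 FPKM. The list's median was -0.029, at percentile 36.6. None of 17 genes for hnRNPs and other omega speckle proteins passed, and 0 had an unadjusted Cuffdiff p of at most 0.05. The largest ratio was that of nonA (7.83 and 5.68 FPKM), Hrb87F stood at 64.6 and 51.8 FPKM, and the median was -0.14, at percentile 4.14. The Ras and polarity list (19 genes) had a median of 0.066, at percentile 84.7, and no member passed. Ras85D was listed at 56.3 and 38.1 FPKM. l(2)gl stood at 56.8 and 112.8 FPKM, and its lowest q in the authors' deposited table was 0.0998, the 1 gene of the list with an unadjusted p of at most 0.05 in the Cuffdiff values. JNK signalling and apoptosis genes (19) had a median of 0.12, at percentile 95.3. None passed, and 1 had an unadjusted Cuffdiff p of at most 0.05: Dronc, an initiator caspase gene, listed at 30.7 and 55.7 FPKM.

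The remaining lists held few calls or none. Of 25 lipid metabolism genes 2 rose, also when adjusted over the list alone: the lipase genes Lip3 (3.63 to 46.1 FPKM) and mag (240.5 to 556 FPKM). This median was 0.065, at percentile 86.3. Of 7 histone genes 1 fell, also when adjusted over the list alone: His2B:CG33868 (46.5 to 14.2 FPKM), a member of a family of near-identical copies whose value is uncertain; the median was -0.071, at percentile 36.5. No gene passed in the insulin list (14 genes, median 0.081, percentile 84.8; Ilp2 at 5.36 and 2.79 FPKM), and 0 had an unadjusted Cuffdiff p of at most 0.05. The proteasome list (47 genes, median -0.014, percentile 52.9) had no call and 1 gene with such a p, Prosbeta2R1 at 6.61 and 1.77 FPKM. The list of neurons and glia (15 genes, median -0.048, percentile 39.2) had no call and 1 such gene, Syt1 at 22.8 and 35.8 FPKM. Odorant binding and chemoreceptor genes (32 genes, median -0.14, percentile 7.25) had no call, and 1 was higher and 2 lower at such a p, with Obp83g at 13.8 and 30.5 FPKM. Testis genes (48 genes, median -0.077, percentile 8.79) had no call and 0 genes with such a p, and Mst77Y-7 stood at 1.73 and 3.60 FPKM. The female germline list held 4 measured genes, too few for a percentile, with orb at 2.97 and 2.28 FPKM, and none was called or had such a p. The dosage compensation RNAs were searched under the bare symbols roX1 and roX2, which gave 0 matches. Other noncoding genes here carry a prefix, as lncRNA:Hsromega does. Both may therefore be listed under another symbol, possibly within the list of long noncoding RNAs, and they were not looked at singly here.

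Noncoding RNAs other than Hsromega moved both ways. Of 621 expressed genes listed by symbol as long noncoding RNAs, 44 of them annotated as pseudogenes and 5 as protein coding, 3 rose and 5 fell, also when adjusted over the list alone, with a median of -0.039 at percentile 42.3. The largest calls were the rise of asRNA:CR45629 and the fall of CR44383, annotated as a pseudogene, from 8.45 FPKM to a listed 0. Small nucleolar and small nuclear RNAs had a median of -0.42, below all 10000 random lists. Of these 128, 1 rose, also when adjusted over the list alone: snRNA:U2:34ABa, a copy of the U2 spliceosomal RNA, from 4645 to 12761 FPKM. U2 genes share near-identical sequence, so this value is uncertain. The list's median is uncertain as well. Its log2 ratios ran from -8.75 to 7.70, with 85 members below 0 and 43 above. Several members overlap a host gene on the same strand, such as snoRNA:Psi28S-3405c in Hrb98DE, so the division of reads between them is uncertain.

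The authors' own classes were set beside these calls. The authors' deposited table classed 134 transcripts as higher and 74 as lower in the mutant, 201 as specific to control and 164 as specific to hsromega66. By the deposited q of at most 0.05, 72 of the 134, 39 of the 74, 21 of the 201 and 7 of the 164 passed, as did 142 transcripts of the authors' baseline class. The values in the classes follow an unadjusted p of at most 0.05 with an absolute log2 ratio of at least 2, and a transcript at 0 in 1 genotype was placed in a specific class whatever its p-value. The highest control-specific transcripts were mir-4945 (654 FPKM), snoRNA:Psi28S-3405c (429 FPKM), snoRNA:Psi28S-1175b (190.1 FPKM), a transcript of CG42460 (173 FPKM) and lncRNA:CR44459 (166 FPKM). The highest specific to hsromega66 were a transcript of Fbp2 (683 FPKM), scaRNA:MeU2-48 (206 FPKM), snoRNA:Psi18S-525i (118 FPKM), and snoRNA:Or-aca1 and snoRNA:Psi28S-3091a (both 49.5 FPKM). All 10 had q = 0.998 in the authors' deposited table, so each is reported only as listed at 0. Fbp2 and CG42460 had other listed transcripts above 0 in both genotypes.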

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

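No paired analysis was possible because the tables hold 1 pooled value per genotype, and for the same reason no replicate could be left out and no set correlation estimated. The count of called genes, 280, stayed within 1.5 times under 8 alternatives, from 216 to 343, and so did the 170 rises and 110 falls. Of these, 3 alternatives were chosen after seeing the data: counting transcripts, leaving out transcripts at 0 in 1 genotype, and keeping genes with 1 listed transcript. Another pseudocount does not enter these calls, which rest on the deposited q. Centring on the median log2 ratio of expressed transcripts, -0.000599, cannot turn a call and tests nothing here. Of 31 tested lists, 13 stood apart, and 14, 14 and 10 did with a pseudocount of 0.1, no filter and a filter of 5 FPKM. Centring shifts a list and its random lists alike and cannot change a percentile. With the filter of 5 FPKM, the immune peptide, cytochrome P450 and cuticle lists no longer stood apart, and fewer genes entered them. The ecdysone list stood apart with a pseudocount of 0.1 and with no filter. No list that stood apart changed sign, nor did a named gene with a pseudocount of 0.1, the 1 alternative run on its ratio. The authors' classes depended most on the threshold. At a deposited q of at most 0.01, 65 of the 134 higher, 31 of the 74 lower, 15 of the 201 control-specific and 7 of the 164 hsromega66-specific transcripts remained, by the construction of a stricter threshold. With an FPKM of at least 1 in at least 1 genotype, 97 of the 164 hsromega66-specific transcripts remained. Leaving out symbols that occur more than once within the authors' class tables kept 128, 72, 182 and 144 transcripts of these 4 classes. Leaving out symbols that occur more than once in the full table, the reading used at first and replaced after its counts were seen, kept 99, 46, 39 and 30. Depth is unknown, so no limit of detection can be given for genes listed at 0.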

Other observations

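Besides e, other enzyme genes of dopamine and beta-alanine metabolism were looked at in hsromega66 larvae. The tyrosine hydroxylase gene ple (60.2 to 184.8 FPKM) and b (black, aspartate decarboxylase; 15.9 to 51.6 FPKM) rose. Ddc was listed at 194 and 327 FPKM and t (tan) at 5.49 and 11.4 FPKM, with q values of 0.585 and 0.198 in the authors' deposited table. AANAT1 (11.5 and 14.4 FPKM) and yellow-f (185 and 108 FPKM) did not pass either, both with q = 0.998 in the authors' deposited table. The genes that rose also included the mucin-related genes Mur18B (59.9 to 175 FPKM), Muc18B (15.5 to 65.3 FPKM), Mur29B (26.8 to 60.0 FPKM), obst-G, named for a chitin-binding protein family (8.99 to 25.8 FPKM) and Cht4 (7.82 to 44.2 FPKM). These genes, and those of the next paragraph, were chosen after their values were seen.

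Further immune genes fell: the thioester protein genes Tep1 (87.7 to 12.1 FPKM) and Tep4 (80.3 to 27.4 FPKM), the serine protease homologue gene SPH93 (442 to 69.5 FPKM), the lectin gene Clect27 (446 to 122.5 FPKM) and the transferrin gene Tsf1 (713 to 280 FPKM). Listericin rose from 60.0 to 273 FPKM, and PGRP-SB2 was listed at 0.146 and 25.4 FPKM with q = 0.998 in the authors' deposited table. Of 40 genes listed at 0 in hsromega66, 20 were called, among them the adjacent genes AANATL5, AANATL6 and AANATL4 (2R, 19284551 to 19289852), at 1.04, 37.7 and 2.14 FPKM in control. Of 30 genes listed at 0 in control, 7 were called, among them the overlapping genes p24-2 (24.0 FPKM) and Unc-115b (4.32 FPKM) in hsromega66. Their copies eca (74.4 and 68.6 FPKM) and Unc-115a (7.69 and 10.8 FPKM) lie beside them, so the division of reads is uncertain. The eye pigment gene w (white) was listed at 22.0 and 0.221 FPKM with q = 0.800 in the authors' deposited table, while ry (rosy) fell from 16.5 to 2.24 FPKM. The noncoding gene lncRNA:CR40469 was listed at 11196 and 5.75 FPKM with q = 0.261 in the authors' deposited table.

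Explanations were then weighed for 3 patterns. The tests on the immune peptides and on the third chromosome as a whole were chosen after their results were seen. So were the interval and the second test for too few reads.

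Hsromega was listed 799-fold lower in the mutant without passing the deposited threshold. If reads shared among the transcripts of a locus widened the deposited test, strongly changed transcripts (absolute log2 ratio of at least 3, at least 10 FPKM) would be called less often at loci with several listed transcripts. This was seen: 16.7% of 60 such transcripts were called, against 54.9% of 51 at loci with 1 listed transcript (Fisher's exact test, two-sided, p = 4.35e-05). The 60 include both Hsromega transcripts themselves and several pairs from the same gene. The units are thus not independent, and the p-value is only a description. In some pairs, such as those of HIP-R and Trax, 1 transcript fell while the other rose, unlike at Hsromega. The 2 groups also differed in how often the lower value lay near 0. None of the strongly changed transcripts with a lower value under 0.305 FPKM was called. This held at loci with 1 listed transcript too, such as PGRP-SB2 (0.146 FPKM in control). Both Hsromega transcripts lay in that range in hsromega66, so for them the test cannot tell shared reads from a value near 0. Shared reads remain a candidate explanation. Too few reads at this expression level were weighed as another explanation. Of 14 falls of at least 3 on the log2 scale at loci with 1 listed transcript, from 10 FPKM in control up to the level of Hsromega, 42.9% were called (exact binomial interval 17.7% to 71.1%). The first rule, under 50% called, would have fitted too few reads, but most of the 14 lay far below Hsromega. A second test took the 63 called falls at loci with 1 listed transcript and above 0 in both genotypes. Of these, 62 had less control FPKM times length and a smaller fall than the main Hsromega transcript. Falls can thus be called at fewer expected reads in control. Because this test took called falls only, it gives no rate of calling. It cannot decide whether too few reads kept the main Hsromega transcript from being called. Above the level of Hsromega, CR40469 was listed with a larger ratio at a locus with 1 listed transcript and was not called. A difference between the libraries of a genotype stays open too, untested here because the values are pooled.

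IM and Drs peptides fell while attacins, diptericin and drosocin rose. Of the 8 fallen peptides, 4 are encoded outside the IM gene cluster of 2R, among them TotC on 3R, within 1 Mb of Hsromega. These 4 had a median log2 ratio of -3.12, so a variant at that cluster cannot be the whole cause. For the 4 in the cluster it cannot be told apart from regulation: the 6 further expressed peptide genes of the same Bom family there were low too (median -2.73), with CG15067 and CG16836 called and CG18107 (-3.71), CG43202 (-1.80), CG15065 (-1.52) and CG15068 (-1.09) not called. The 20 other expressed genes within 100 kb had a median of -0.092, and 2 of them fell, GstE3 (256 to 96.3 FPKM) and GstE8 (10.3 to 2.77 FPKM). Before the family members were set apart, the 26 together had a median of -0.19. A local variant or shared regulation of the cluster would both leave such values. Less fat body tissue is argued against by the fat body list, whose median was -0.019 and whose lowest member was at -0.58, above the smallest peptide fall of -1.83. The Hsromega genotype, the stocks' backgrounds and a difference in microbial exposure between the stocks' cultures may each have set these levels; they were not tested, and the design cannot separate them.

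The rise of e near Hsromega may come from a segment of another strain carried with the mutation. Within 1 Mb of Hsromega, 4.62% of 195 genes were called, against 2.30% of 2738 in the rest of 3R, with 16 genes of 3R left out for want of matched coordinates (Fisher's exact test, two-sided, p = 0.0533), so the 9 calls there are too few to decide. Among the 9 are e itself, lncRNA:CR46046, TotC and MtnB. The 195 include the 16 mod(mdg4) entries, which overlap and are not independent. Another origin of the whole chromosome was no better resolved: 2.43% of 5343 genes on 3L and 3R were called, against 2.25% of 6652 on 2L, 2R and X (Fisher's exact test, two-sided, p = 0.543). The arms of the latter differed, with 1.78% on 2L, 1.49% on X and 3.24% on 2R, the highest of these 5 arms. The comparison could show another origin of the third chromosome only if the stocks share the other chromosomes. Nothing in the labels says so, and the comparison therefore cannot decide. Effects of the Hsromega mutation on e and of stock background cannot be told apart in these data, since each genotype is 1 stock.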
